A study of Mus musculus with 2 samples.

How the data were processed

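The data are DNase-seq libraries from the frontal cortex of female B6CASTF1/J mice at 25 days of age, 1 group of 2 libraries. Replicate numbers are those of the labels. Nuclei were isolated from tissue, per the labels' protocols. The aligner, the peak and footprint callers, their versions and the sequencing depth are not given in the sources used here.

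Per the text files deposited with each library, all files are on mm10, and peaks, footprints and the false discovery rate of the cut rate were derived from that library's own alignment, so peaks were called per library and not on pooled libraries. Each library has 2 peak lists in which column 7 is the authors' signal per peak, read-depth normalized on a scale that is not stated. All values (100%) lay within 0.1 of a whole multiple of 1 step, 0.00565 in replicate 1 and 0.00571 in replicate 2, and the weakest peak had 6 steps in each, the median peak 111 and 119. The deposited peak lists hold no p-value or q-value. A deposited table gives the false discovery rate (a q-value) of the cut rate for each position, and lists those of at most 0.05. Each peak of the longer list held a position with a false discovery rate of at most 0.05, and each peak of the shorter list one under 0.001. The shorter lists hold 47874 and 50077 peaks. The authors' footprint lists carry 1 constant, 0.01, read here as the threshold of the call. The longer peak list was the main list, by a rule fixed in advance (the longer list where widths were equal); within each library the median widths of its lists were equal.

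The reference was the GRCm38.p6 genome with the GENCODE vM21 annotation, the same build as mm10. All intervals lay on the 21 chromosomes and none passed a chromosome end. The annotation holds 55413 genes, of which 21938 are protein-coding. A peak was at a promoter when its centre lay within 1 kb of a TSS of any annotated transcript of a protein-coding gene, otherwise in an exon, an intron or intergenic sequence. A gene had a promoter peak when a peak overlapped the 1 kb on either side of any of its annotated TSS by at least 1 bp, so that a peak can count for neighbouring genes: among the 212 list entries with a promoter peak in both libraries, the strongest peak of 12 was also within 1 kb of a TSS of another protein-coding gene. The promoter value of a gene was that of its strongest promoter peak, averaged over the libraries. CpG content was counted in the 1 kb around the annotated 5' end of the gene, whichever TSS had the peak. Overlaps between libraries needed at least 1 bp, and chance levels came from 100 random circular shifts within each chromosome. For footprints in shared regions, chance came from rotating footprints within the region.

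The gene lists, motifs, tests and main settings and the alternatives were fixed before the data were examined, except where stated. There were 28 lists: pan-neuronal, excitatory neurons, cortical layers, inhibitory neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, meningeal fibroblasts, choroid plexus and ependyma, striatal neurons, immediate early genes, glutamate receptors, GABA-A receptors, forebrain factors, midbrain and hindbrain factors, Hox genes, neural progenitors, liver, striated muscle and heart, erythroid cells, lymphocytes, germ cells, housekeeping, circadian clock, X inactivation and escape, and imprinted genes. They hold 369 genes by symbol, of which 1 (Ahsp) was not matched in the annotation, and Ctgf was read as Ccn2. A two-sided Fisher's exact test compared the share of a list's genes with a promoter peak in both libraries with that of all other genes of the list's biotypes, and p-values were adjusted over the lists by the Benjamini-Hochberg method with a threshold of 0.05. Peak numbers in the gene body and 10 kb on each side were compared with 10000 random lists of the same size matched on gene length in 20 bins, with a two-sided permutation p of at least 0.0002. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error over genes only.

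The genes named were, for each list, up to 4 with the largest promoter value among those with a promoter peak in both libraries, up to 3 with none in either library in list order, each with a peak in 1 library only, Xist and Tsix, and the 10 protein-coding genes of at least 10 kb with the most peaks per 100 kb. Motifs were 23 consensus sequences, counted on both strands in footprints and in the rest of the peaks and compared with up to 100 letter permutations of the same consensus (8 for SP/KLF and 13 for the homeodomain motif, which have fewer distinct ones), with 1 added to each count before the ratio. The scans and list tests were tested on simulated data, the lists at an unadjusted threshold of 0.05. Of 100 random lists of 13 genes among 21938, 2% were called for promoter peak share with no effect. With all members set to have a peak 100% were called, which that setting fixes in advance. Promoter peaks were shuffled over genes, which removes their dependence on CpG content. For peak number 3% were called with no effect, and 94% with peak numbers raised 3-fold plus 1. Of 500 planted motif occurrences 100% were found, in simulated footprints wider than most real ones.

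The alternatives were other promoter windows (500 bp and 2.5 kb), 1 TSS per gene, the shorter peak list, the 50% of peaks with the highest value, equal peak numbers, an overlap of at least 50% of both intervals, genes matched on promoter CpG content in 10 bins, the gene body alone or with 50 kb on each side, peaks outside promoters, widened footprints, footprints outside promoters, stricter false discovery rates and each library alone. Chosen after the data had been seen were the alternatives without windows of 50 kb that held 10 or more regions of 1 library only and with peaks overlapping the other library alone, the gene families, the motif scan of distal regions, the test on genes of the Y short arm and the tests of a lower local calling threshold. Values of some members of the gene lists are not reported. Copies of a region were sought with BLAST+ 2.17.0 as matches of at least 95% identity over at least 90% of its length. Computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, pysam 0.24.0, Numba 0.67.0 and Matplotlib 3.10.9, and bedtools 2.31.1 and samtools 1.23.1.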

Results

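Open chromatin was mapped by DNase-seq, in which the enzyme DNase I cuts DNA that is not shielded by nucleosomes and the cut ends are sequenced. The tissue was the frontal cortex of female mice of the B6CASTF1/J strain at 25 days of age, the F1 cross of C57BL/6J and the wild-derived CAST/EiJ strain. There was 1 group with 2 libraries, replicate 1 and replicate 2, and no comparison between conditions. The labels name them as separate biological replicates with separate biosamples but give a single donor identifier for both, so the spread between them is a spread between samples that need not be one between animals. The authors called 85603 peaks in replicate 1, covering 17.6 Mb at a median width of 200 bp, and 87847 peaks in replicate 2, covering 16.7 Mb at a median width of 190 bp. Each peak carries the authors' read-depth normalized signal, called its value here, with a median of 0.627 in replicate 1 and 0.679 in replicate 2. All coordinates are on mm10.

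The strongest region called in both libraries that was also a promoter lay at the start of Hjurp, which encodes the chaperone of the centromeric histone CENP-A, and of the cold-sensing channel gene Trpm8 (chromosome 1, 88277521 to 88277760), with values of 15.2 and 15.7. The promoters of the dynein light chain gene Dynlt1b, of Bahcc1, of Acin1 and of the splicing factor gene Snrnp70 were also among the 20 regions with the highest mean value. The highest of all lay on chromosome 17 from 39846781 to 39846920, in an annotated exon 103669 bp from the nearest protein-coding transcription start site (TSS), that of Esp38, with values of 49.6 and 32.8. Several of these 20 regions were far apart in the libraries, such as chromosome 9 from 3002021 to 3002220 with values of 31.7 and 5.43. Of the 20 regions, 10 had another near-identical copy in the genome. Among these 10 were the highest, with 1 other copy, that on chromosome 9, with 121, and that at Dynlt1b. Of the peaks of replicate 1, 71.0% overlapped a peak of replicate 2 by at least 1 bp, and 69.7% of the peaks of replicate 2 overlapped one of replicate 1. Peaks shifted at random around their chromosomes overlapped in 1.36% and 1.32%, so the observed shares were 52.0-fold and 52.9-fold the chance level.

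Merging both lists gave 109538 regions, of which 58659 (53.6%) were called in both libraries, 24456 in replicate 1 only and 26423 in replicate 2 only. Across the shared regions the values had a Spearman's rho of 0.908, given as a description since regions are not independent replicates. The log2 ratio of replicate 1 to replicate 2 had an SD of 0.39, against a median of 0.17 if each step of the value scale were 1 read and counting were the only error, and 1.75% of shared regions differed by more than 2-fold. Regions of 1 library only were weaker, with median values of 0.390 in replicate 1 and 0.411 in replicate 2 against 0.825 and 0.908 in shared regions. They were also less often at promoters, at 23.7% and 15.5% against 33.8%.

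**Figure D1:**
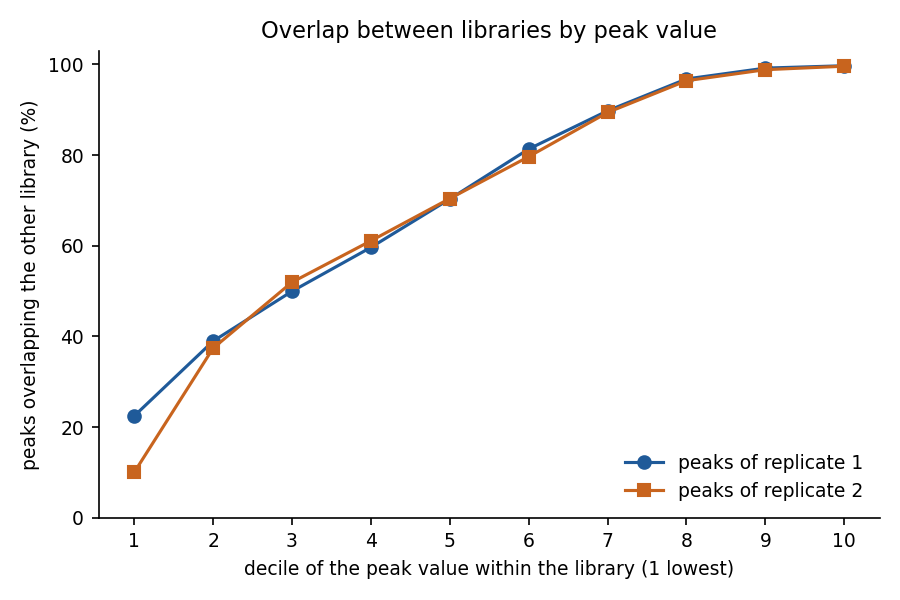
The share of each library's peaks that overlapped a peak of the other library (vertical axis, %) is plotted against the decile of the peak value within the library (horizontal axis, 1 lowest), with 1 line per library. Overlap went from 22.5% (replicate 1) and 10.01% (replicate 2) in the lowest decile to 99.7% and 99.6% in the highest.

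Promoters, taken as the 1 kb on either side of a TSS of a protein-coding gene, held 30.5 ± 1.80% of peak centres (SD, n = 2), 8.06-fold and 7.42-fold the share of shifted peaks in the respective libraries. Exons held 5.75 ± 0.0180%, introns 32.5 ± 1.12% and intergenic sequence 31.2 ± 0.693% (SD, n = 2). Exons were at 1.45-fold the shifted share in both libraries, introns at 0.775-fold and 0.813-fold, and intergenic sequence at 0.601-fold and 0.620-fold. Promoters and exons were above the highest of the 100 shifts. Promoter peaks were stronger than other peaks, with median values of 0.921 against 0.548 in replicate 1 and 1.03 against 0.605 in replicate 2. They were also wider, at medians of 240 bp and 220 bp against 180 bp elsewhere in both libraries.

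Of 21938 protein-coding genes, 13489 (61.5%) had a peak within 1 kb of a TSS in both libraries, 575 in replicate 1 only, 303 in replicate 2 only and 7571 (34.5%) in neither. The share depended on the CpG content of the promoter, the density of the dinucleotide that marks CpG islands. It was 3.62% among genes in the lowest of 10 bins, with at most 4 CpG in the 1 kb around the gene's 5' end. In the highest bin, with 92 or more, it was 95.4%. Among genes with a promoter peak in both libraries the median of the strongest promoter value was 2.34 and the 90th percentile 4.89. For the gene lists fixed in advance, a gene was counted where both libraries had a promoter peak, and each list was compared with all other genes of the same biotypes, of which 61.5% had one unless another share is given. Genes, not animals, were the units of these tests.

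Genes that all neurons use were open at their promoters without exception. All 13 pan-neuronal genes had a promoter peak in both libraries, led by the synaptic vesicle calcium sensor Syt1 at 2.97 ± 0.882, the postsynaptic scaffold gene Dlg4 at 2.41 ± 0.801, the neuronal tubulin Tubb3 at 2.40 ± 0.150 and the dendritic microtubule protein Map2 at 2.09 ± 0.172 (mean ± SD, n = 2, as for all promoter values that follow). All 12 genes of excitatory neurons had one too, among them the kinase gene Camk2a at 2.35 ± 0.724, Nrgn at 2.34 ± 0.495 and Neurod2 at 1.56 ± 0.469. Most values were moderate, with 10 of the 13 pan-neuronal and 9 of the 12 excitatory genes below the median of 2.34 over all genes with a promoter peak. Both shares of 100% stood above other genes by Fisher's exact test, with adjusted p = 0.0126 and 0.0197 over the 28 lists (exact Clopper-Pearson 95% intervals 75.3 to 100% and 73.5 to 100%). Both also passed against random genes matched on promoter CpG content, which had a promoter peak in 73.6% and 63.9% of draws (adjusted permutation p = 0.0280 and 0.0182). CpG was counted at the gene's 5' end, while the strongest replicate 1 peaks of Rbfox3 and Dlg4 (7 and 10 CpG) lay at another TSS. With 1 TSS per gene neither list passed (Fisher's exact test, adjusted p = 0.0947 and 0.307), and CpG matching was not run there. Excitatory genes did not pass on the shorter, stricter peak list (exact adjusted p = 0.610).

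Genes that mark the layers of the cortex had a promoter peak in 13 of 14 cases. The corepressor gene Tle4, a marker of deep-layer neurons, had the highest value at 9.07 ± 3.16, followed by Pou3f1 at 2.03 ± 0.272, the layer 5 factor Bcl11b at 1.67 ± 0.129 and the layer 4 receptor gene Rorb at 1.64 ± 0.350. Of the 13 values 12 lay below that median. Fezf2, which specifies subcerebral projection neurons, had none in either library. Glutamate receptor genes had one in 19 of 22 cases, with Gria2 at 2.96 ± 1.05, Grm8 at 2.74 ± 0.281, Grin1 at 2.52 ± 0.874 and Grik4 at 2.06 ± 0.262. Grin2c, a subunit gene used mainly in the cerebellum, and Grm6, the receptor gene of retinal bipolar cells, had none, and Grm2 had one in replicate 1 only (0.667). Both lists passed at adjusted p = 0.0310 (Fisher's exact test). Neither passed against CpG-matched genes (adjusted permutation p = 0.307 for both), and they passed in 2 and 3 of the 8 other settings tried.

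Subunit genes of the GABA-A receptor, the main inhibitory receptor of the brain, had a promoter peak in 11 of 13 cases, among them Gabrb1 at 1.48 ± 0.182, Gabra2 at 1.40 ± 0.142 and Gabrb2 at 1.25 ± 0.103. Gabra6, a subunit gene of cerebellar granule cells, had none, and Gabrd had one in replicate 1 only (0.729). Markers of striatal neurons, a forebrain population outside the cortex, had one in 9 of 10 cases, among them Rgs9 at 3.01 ± 0.633, Pde10a at 2.08 ± 0.0167 and the dopamine receptor gene Drd1 at 2.06 ± 0.153, while Drd2 had none. Inhibitory neuron genes had one in 10 of 15 cases, with Adarb2 at 1.47 ± 0.449, Dlx5 at 1.12 ± 0.189, Dlx1 at 1.06 ± 0.177 and the GABA synthesis gene Gad1 at 1.03 ± 0.273. The neuropeptide genes Sst and Vip and the interneuron factor Lhx6 had none, Dlx2 had one in replicate 1 only (0.876) and Dlx6 in replicate 2 only (1.27). None of these 3 lists passed (Fisher's exact test, adjusted p = 0.176, 0.122 and 0.824). On the stricter peak list, however, 3 of the 15 inhibitory genes (20%) had a promoter peak against 55.6% of other genes, and that lower share passed (exact adjusted p = 0.0183). It did not on the main list against CpG-matched genes, with 66.7% against 74.2% (adjusted permutation p = 0.805).

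**Figure D2:**
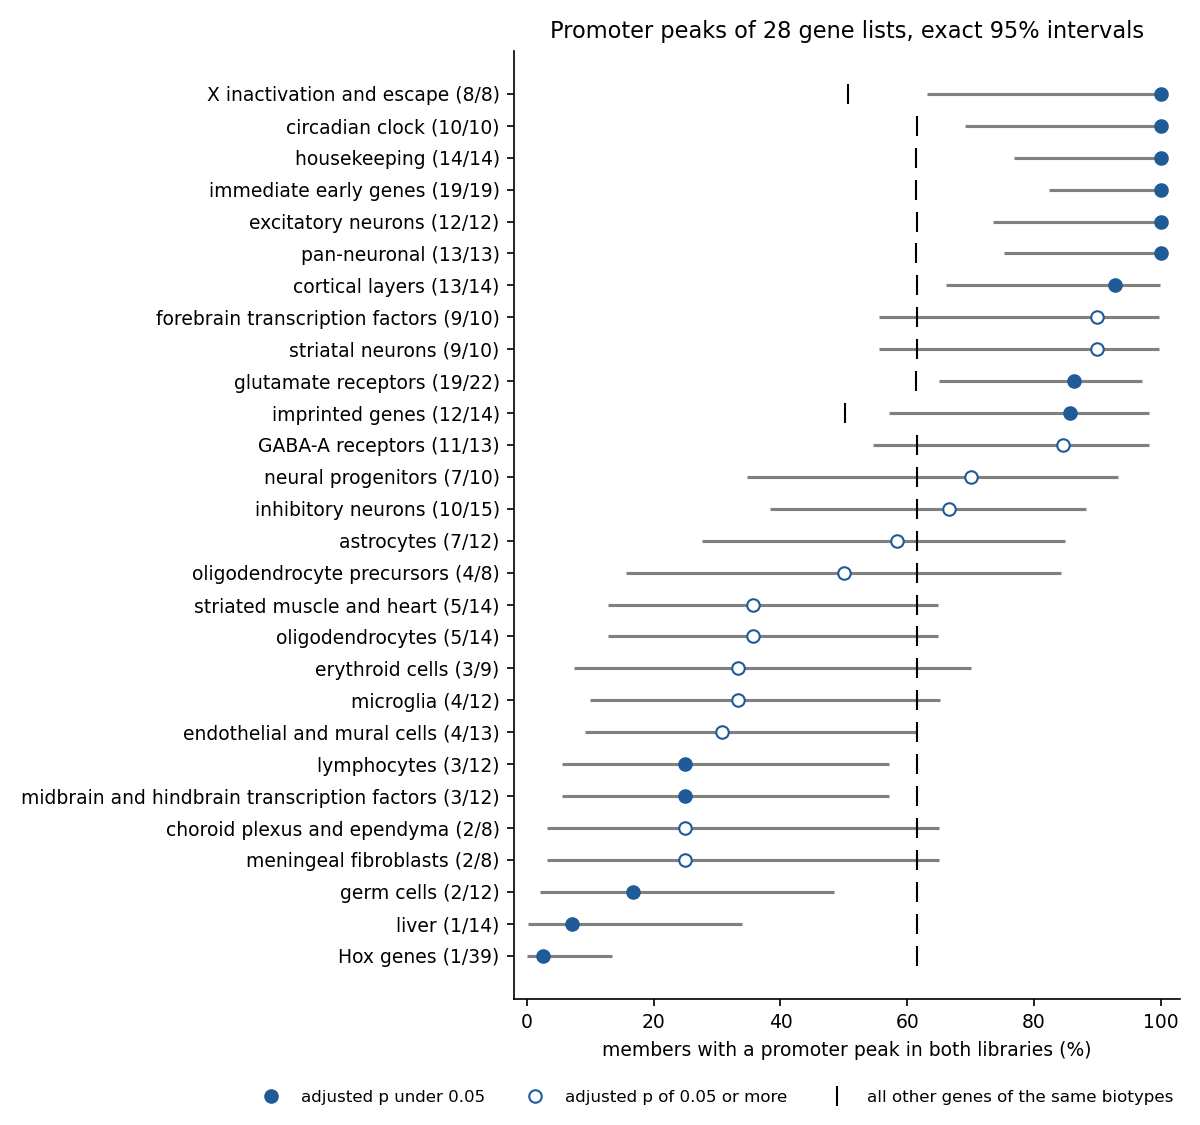
Each point is the share of a gene list's members with a promoter peak in both libraries (horizontal axis, %; members with a peak and list size in brackets), with its exact Clopper-Pearson 95% interval; vertical ticks are all other genes of the same biotypes. Filled points are the 14 lists with an adjusted p under 0.05 in Fisher's exact test, from 2.56% of Hox genes to 100% of 6 lists.

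Markers of glia, vessels and the brain's borders had a promoter peak in both libraries in at most 58.3% of a list's genes. In replicate 1 alone it was 91.7% for astrocytes (11 of 12) and 50% for the choroid plexus list (4 of 8). Of 12 astrocyte genes 7 had a promoter peak in both libraries, among them the glial transcription factor Sox9 at 1.63 ± 0.221, the intermediate filament Gfap at 1.62 ± 0.498, the glutamate transporter Slc1a2 at 1.41 ± 0.0787 and Aldoc at 1.27 ± 0.226. The water channel gene Aqp4 (0.305), Gja1 (0.373), Fgfr3 (0.633) and Gjb6 (0.441) had one in replicate 1 only, and Aldh1l1 had none. Of 14 oligodendrocyte genes 5 had one, with the lineage factors Olig1 at 1.35 ± 0.126 and Olig2 at 0.948 ± 0.549, Cnp at 1.02 ± 0.161 and the myelin regulator Myrf at 0.972 ± 0.216. The myelin genes Mog and Mag had none, and Ermn (0.314) and Nkx6-2 (0.605) had one in replicate 2 only. Of 8 genes of oligodendrocyte precursors 4 had one, with Tnr at 1.84 ± 0.419, the growth factor receptor Pdgfra at 1.76 ± 0.0231, Ptprz1 at 0.818 ± 0.0984 and Bcas1 at 0.555 ± 0.201. Cspg4 and Neu4 had none, Gpr17 had one in replicate 2 only (0.628) and Enpp6 in replicate 1 only (0.266).

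Microglia genes, those of the brain's resident macrophages, had a promoter peak in 4 of 12 cases, among them the complement gene C1qc at 1.03 ± 0.0366, Trem2 at 0.497 ± 0.0485 and Cx3cr1 at 0.426 ± 0.132. P2ry12, Tmem119 and the growth factor receptor Csf1r had none, and Aif1 had one in replicate 2 only (0.999). Endothelial and mural genes had one in 4 of 13 cases, with the glucose transporter Slc2a1 at 2.30 ± 0.507, Rgs5 at 0.528 ± 0.0280, Flt1 at 0.497 ± 0.0807 and Kcnj8 at 0.415 ± 0.0513. Pecam1, Cdh5 and Tek had none, and the tight junction gene Cldn5 had one in replicate 2 only (0.428). Meningeal fibroblast genes had one in 2 of 8 cases, Col1a1 at 2.17 ± 0.245 and Foxc1 at 0.895 ± 0.00542, while Col1a2, Col3a1 and Lum had none and Dcn had one in replicate 2 only (0.240). Genes of the choroid plexus and ependyma had one in 2 of 8 cases, the cilia factor Foxj1 at 4.29 ± 0.309 and Kl at 0.705 ± 0.0615, while Ttr, Folr1 and Clic6 had none and Otx2 (0.463) and Ccdc153 (0.757) had one in replicate 1 only.

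None of these 7 glial, vascular and border lists passed by Fisher's exact test, with adjusted p = 1 for astrocytes, 0.0908 for oligodendrocytes, 0.554 for their precursors, 0.0988 for microglia, 0.0767 for endothelial and mural cells, and 0.0908 for both meningeal and choroid plexus genes. On the stricter peak list the lower shares of microglia (2 of 12), endothelial and mural (2 of 13), meningeal and choroid plexus genes did pass (exact adjusted p = 0.0183, 0.0128, 0.0460 and 0.0460). Against CpG-matched genes on the main list they did not (adjusted permutation p = 1, 0.235, 1 and 0.277), and for microglia the shares were 33.3% and 35.0%. Microglia genes also passed with promoters of 500 bp on each side and for the stronger 50% of peaks (exact adjusted p = 0.0335 and 0.0185), choroid plexus genes with the former (exact adjusted p = 0.0190), and endothelial and mural genes with the latter and in replicate 1 alone (exact adjusted p = 0.00270 and 0.0390). With lists of 8 to 15 genes a share has to lie far from that of other genes to pass.

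Promoters of forebrain transcription factors were open in 9 of 10 cases by any annotated TSS, and those of Hox genes were nearly all without a peak. The forebrain factors with a promoter peak included Lhx2 at 1.72 ± 0.149, Pax6 at 1.67 ± 0.113 and Emx1 at 1.09 ± 0.0682, and Nr2f1 had one in replicate 2 only (0.794). With 1 TSS per gene, and on the stricter peak list, 5 of the 10 forebrain factors had one, with log2 odds ratios of -0.39 and -0.33 against 1.99. Midbrain and hindbrain factors had one in 3 of 12 cases, among them Pax5 at 0.949 ± 0.0171 and Atoh1 at 0.403 ± 0.00299. En1, Gbx2 and Pax8 had none, and En2 (0.435) and Pax2 (0.345) had one in replicate 1 only. Hox genes, which pattern the hindbrain and spinal cord, had one in 1 of 39 cases, Hoxa7 at 1.40 ± 0.0699 (chromosome 6, 52221701 to 52221940), and Hoxc5 had one in replicate 1 only (0.520). Hoxa2 and Hoxa3 were among the others, which had none in either library. With promoters of 2.5 kb on each side 5 of the 39 Hox genes (12.8%) had one in both libraries.

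Hox genes (2.56%, exact 95% interval 0.0649 to 13.5%) stood furthest below other genes, with adjusted p = 1.16e-13 by Fisher's exact test. Midbrain and hindbrain factors (25%, exact 95% interval 5.49 to 57.2%) passed at adjusted p = 0.0310, and forebrain factors did not (exact adjusted p = 0.122) except in replicate 2 alone (exact adjusted p = 0.0365) and with promoters of 2.5 kb on each side (exact adjusted p = 0.0452). Many of these promoters are rich in CpG, and genes matched on it had a peak in 81.9% and 82.3% of draws, so that Hox and midbrain and hindbrain genes both passed there at adjusted permutation p = 0.00280, from the smallest raw p these draws can give, 0.0002. The midbrain and hindbrain call was lost in replicate 1 alone (exact adjusted p = 0.155) and with promoters of 2.5 kb on each side (exact adjusted p = 0.0544). Hox genes lie in clusters and are not independent units.

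Progenitor genes had a promoter peak in 7 of 10 cases and did not pass (Fisher's exact test, adjusted p = 0.808). The proliferation genes Top2a at 4.54 ± 1.05 and Mki67 at 1.03 ± 0.0446 and the stem cell factors Sox2 at 1.33 ± 0.295 and Hes5 at 1.17 ± 0.165 were among them. Eomes, the factor of intermediate progenitors, had none, and Nes (0.780) and Neurog2 (0.379) had one in replicate 1 only.

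Genes specific to other organs mostly had no promoter peak. Liver genes had a promoter peak in 1 of 14 cases, the apolipoprotein gene Apob at 1.57 ± 0.225, while albumin (Alb), Apoa1 and Cyp3a11 had none. Germ cell genes had one in 2 of 12 cases, Gdf9 at 6.28 ± 1.62 and Dazl at 1.07 ± 0.0885, while Ddx4, Sycp3 and Prm1 had none; the peak at Gdf9 was also within 1 kb of the TSS of Uqcrq, a subunit gene of respiratory complex III. Lymphocyte genes had one in 3 of 12 cases, Foxp3 at 4.68 ± 1.42, Lck at 1.13 ± 0.0438 and Ebf1 at 0.844 ± 0.0344, and the peak at Foxp3 was within 1 kb of a TSS of Ppp1r3f, while Cd3e, Cd3d and Cd4 had none. Liver, germ cell and lymphocyte genes passed (Fisher's exact test, adjusted p = 0.000514, 0.0112 and 0.0310). Against CpG-matched genes only the germ cell list of these 3 passed (adjusted permutation p = 0.0182, against 0.171 for liver and 0.688 for lymphocytes). The lymphocyte call was also lost on the stricter peak list and for the stronger 50% of peaks (exact adjusted p = 0.0684 and 0.0730).

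Muscle and heart genes had a promoter peak in 5 of 14 cases and erythroid genes in 3 of 9, and neither list passed (Fisher's exact test, adjusted p = 0.0908 and 0.122). The muscle genes included Mylpf at 2.87 ± 1.19, whose peak was within 1 kb of a TSS of Tbc1d10b, Ckm at 1.66 ± 0.474, Des at 1.03 ± 0.000368 and Myh7 at 0.744 ± 0.00552. Myh6, Nppa and Tnnt2 had none and Tnni3 had one in replicate 1 only (0.542). The erythroid genes included Epor at 1.19 ± 0.218 and Tal1 at 0.621 ± 0.297, while Gata1, Klf1 and the globin gene Hbb-bs had none. On the stricter peak list muscle genes did stand below other genes (exact adjusted p = 0.0288), as they did with promoters of 500 bp on each side and with 1 TSS per gene (exact adjusted p = 0.00451 and 0.0427), and erythroid genes did for the stronger 50% of peaks (exact adjusted p = 0.0287). Against CpG-matched genes neither list passed (adjusted permutation p = 0.307 and 1).

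Genes that neuronal activity induces within minutes were open throughout. All 19 immediate early genes had a promoter peak in both libraries, with Jun, a subunit of the AP-1 factor, at 6.93 ± 2.10, Egr1 at 4.83 ± 0.269, the synaptic scaffold gene Homer1 at 4.49 ± 0.00117 and Arc at 4.38 ± 0.603, while 7 of the 19 lay below the median of 2.34 over all genes with a promoter peak. All 10 circadian clock genes had one, with Nr1d1 at 7.46 ± 2.24, Per1 at 7.16 ± 2.02, Per2 at 6.50 ± 1.43 and Dbp at 6.31 ± 1.81, and each of these 4 exceeded the 90th percentile of promoter values. All 14 housekeeping genes had one, with the ribosomal protein gene Rplp0 at 8.59 ± 0.274, Ppia at 5.59 ± 0.700, Gapdh at 5.03 ± 0.600 and Tbp at 4.96 ± 0.105, the last within 1 kb of a TSS of Psmb1. The shares of 100% passed in all 3 lists (Fisher's exact test, adjusted p = 0.00145, 0.0278 and 0.0105). They did not pass against CpG-matched genes, of which 87.6%, 90.7% and 80.1% had a promoter peak (adjusted permutation p = 0.277, 0.921 and 0.120), and housekeeping genes did not pass with 1 TSS per gene (exact adjusted p = 0.0724).

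Genes of X inactivation and of escape from it had a promoter peak in 8 of 8 cases, against 50.6% of genes of the same biotypes. The histone demethylase genes Kdm6a at 8.92 ± 2.52 and Kdm5c at 5.07 ± 1.55 and the helicase gene Ddx3x at 3.70 ± 0.0354, which escape silencing, and the noncoding gene Ftx at 5.19 ± 1.81 had the highest values. Xist, whose RNA coats the inactive X, was at 0.987 ± 0.274 and its antisense gene Tsix at 0.421 ± 0.0593. Imprinted genes, expressed from 1 parental copy, had one in 12 of 14 cases against 50.2%, with Kcnq1ot1 at 3.34 ± 0.651, Peg3 at 3.27 ± 0.868, whose peak was within 1 kb of a TSS of Usp29, Meg3 at 2.61 ± 1.36 and Zim1 at 2.35 ± 0.744, while Igf2 had none and H19 had one in replicate 1 only (0.299). Both lists passed (Fisher's exact test, adjusted p = 0.0275 and 0.0310), and imprinted genes also passed against CpG-matched genes (adjusted permutation p = 0.0280). The list of X inactivation did not (adjusted permutation p = 0.281), and neither list passed with 1 TSS per gene (exact adjusted p = 0.0724 and 0.331). Imprinted genes did not pass with promoters of 2.5 kb on each side either (exact adjusted p = 0.0524).

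Of the 28 lists, 5 held more peaks than genes of matched length, promoter peaks included. Immediate early genes had a median of 8 peaks in the gene body and 10 kb on each side, against 2 in random genes of matched length, and circadian genes had 7.75 against 3.25. Excitatory neuron genes had 9.75 against 3.75, pan-neuronal genes 9.5 against 5 and housekeeping genes 5.25 against 2.25. These 5 lists passed a two-sided permutation test on 10000 random lists, at adjusted p = 0.00280, 0.00560, 0.00280, 0.0426 and 0.00700, and the raw p of immediate early and excitatory genes, 0.0002, is the smallest these permutations can give. Liver genes had a median of 0.75 against 2.5 and did not pass after adjustment (permutation p = 0.0292, adjusted p = 0.136), and no other list passed.

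Several of these 5 calls depended on the setting. With 50 kb on each side none passed (adjusted permutation p of 0.0832 for each of the 5), the pan-neuronal call was lost in replicate 2 alone (adjusted permutation p = 0.0941), and the pan-neuronal and excitatory calls were lost on the stricter peak list (adjusted permutation p = 0.0896 and 0.356). With promoter peaks left out, housekeeping and pan-neuronal genes did not pass (adjusted permutation p = 0.892 and 0.161), and oligodendrocyte and X inactivation genes did (adjusted permutation p = 0.0336 for both). With the gene body alone, housekeeping and pan-neuronal genes did not pass (adjusted permutation p = 0.0538 for both). The excitatory call was also lost for the stronger 50% of peaks and for peaks overlapping the other library alone (adjusted permutation p = 0.0694 and 0.385). Of 9 alternatives, pan-neuronal genes passed in 2, excitatory genes in 5, housekeeping genes in 6, and immediate early and circadian genes in 8.

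The genes with the densest peaks, among those of at least 10 kb, were Acap3, a gene of an Arf GTPase-activating protein, with 102 peaks per 100 kb of gene and flanks in the mean of both libraries (29 peaks in replicate 1 and 43 in replicate 2), Blcap with 77.3, Gm49027 with 76.3, Leng8 with 75.5 and Vps33a, a gene of vesicle fusion, with 74.6. Nup62 with 72.0, Mxd4 with 70.9, the morphogen gene Shh with 69.0, the apoptosis gene Diablo with 68.3 and Ttyh1 with 65.7 completed the 10, against a median of 5.51 over all such genes. Gm49027, Diablo and Vps33a overlap or share flanks on chromosome 5, as do Leng8 and Ttyh1 on chromosome 7. A peak there can count for more than 1 of the 10. The libraries differed at several of the 10 genes, as at Shh with 12 and 30 peaks. With peaks overlapping the other library alone, a setting chosen after the results were seen, 8 of the 10 remained among the 10 densest. Once only the stronger 50% of peaks were kept, none of the 10 remained among the 10 densest, which then included Kdm6b, Smarcd1, Dapk3 and Per1.

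The X chromosome held fewer peaks per Mb than any autosome. It had 13.4 peaks per Mb in replicate 1 and 13.3 in replicate 2, against 33.8 and 34.7 on the autosomes together, a ratio of 0.389 ± 0.00913 (SD, n = 2). The lowest autosome was chromosome 3 at 26.9 and 26.8 and the highest chromosome 11 at 47.2 and 47.3. Per protein-coding gene the ratio was 0.603 and 0.583, and there too X, at 2.41 and 2.40 peaks per gene, was below the lowest autosome, chromosome 7 at 2.68 and 2.80. With the stronger 50% of peaks alone the ratio per Mb was 0.243. Chromosome Y, in libraries labelled female, held 60 and 36 peaks with median values of 0.203 and 0.108.

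**Figure D3:**
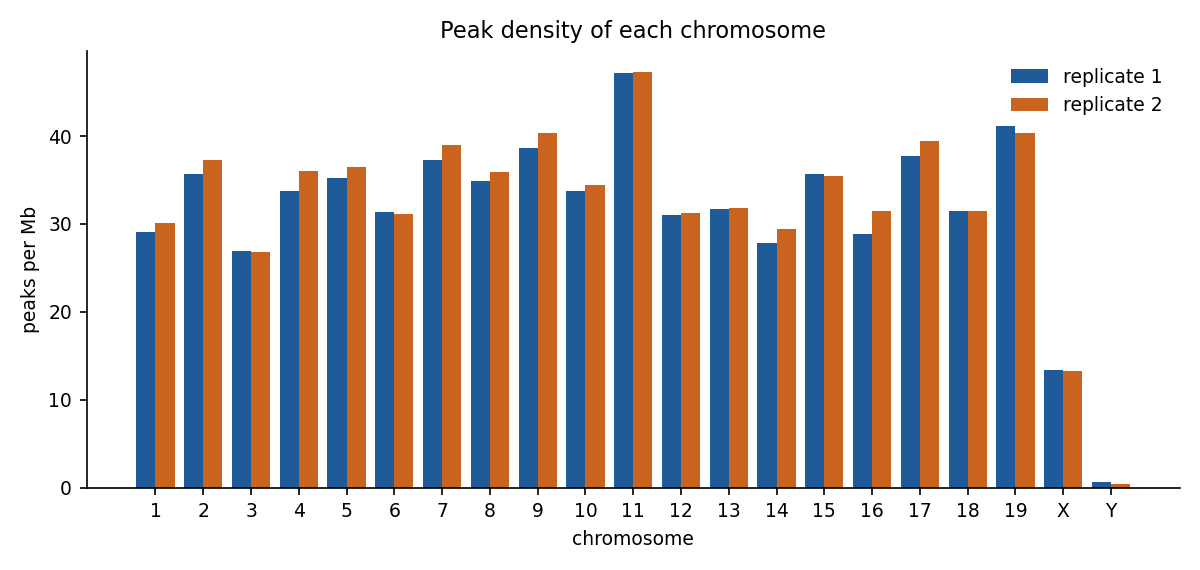
Bars give the number of peaks per Mb (vertical axis) on each chromosome (horizontal axis) in replicate 1 (blue) and replicate 2 (orange). X, at 13.4 and 13.3, lies below every autosome, the lowest of which is chromosome 3 at 26.9 and 26.8.

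Footprints, short stretches inside open chromatin where a bound protein shields DNA from the enzyme, numbered 214072 in replicate 1 and 189951 in replicate 2, with a median width of 9 bp in both. Promoter peaks held 3.11 and 2.78 footprints each, other peaks 1.88 and 1.67. Per 100 bp of peak these were 1.18 and 1.20 at promoters against 1.01 and 0.953 elsewhere. Of the footprints 89.2% and 91.7% overlapped a peak of their library by at least 1 bp, against 0.751% and 0.718% after random shifts. Both were derived from the same alignment, so this excess is no independent support for the footprints. At least 1 footprint overlapped 80.6% and 78.9% of peaks. Of the footprints, 43.6% in replicate 1 and 49.5% in replicate 2 overlapped one of the other library. Within regions called in both libraries the shares were 52.2% and 57.5%, against 29.2% and 31.9% when footprints were rotated within their region.

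The binding site of CTCF, the insulator protein that anchors chromatin loops, was the most frequent of 23 consensus motifs in the footprints as called. It had 4792 and 4247 occurrences there and a log2 density ratio over the rest of the peaks of 5.82 and 5.38 in the 2 libraries. NRF1, a regulator of mitochondrial and housekeeping genes, had 418 and 397 occurrences and log2 ratios of 6.15 and 5.60, and the palindromic site of NFI, a family of factors in neurons and glia, had 40 and 48 occurrences and ratios of 2.98 and 4.05. These 3 motifs exceeded all 100 letter-permuted versions of themselves in both libraries, whose highest mean ratios were 3.16, 2.82 and 2.57, and NFI did not outside promoters. For NFI the 2.57 equals the ratio that 0 occurrences give after 1 is added to each count. NFI is thus the weakest of the 3 calls, with 40 occurrences in footprints and 29 in the rest in replicate 1. The CRE motif of activity-regulated CREB (3.47 and 2.98), the EGR motif (3.66 and 3.38), RFX (2.62 and 2.72) and YY1 (1.99 and 1.76) exceeded 99 of 100, and the bHLH motif of NEUROD (1.28 and 1.22) exceeded 98. The AP-1 motif (-0.72 and -0.63), MEF2 (-0.82 and -1.69) and the homeodomain motif TAATTA (-1.35 and -2.07) were rarer per bp in footprints than in the rest of the peaks and did not stand above their permuted versions. In the mean of the libraries these 3 were at -0.67, -1.26 and -1.71, and the medians of their permuted versions at -0.68, -1.34 and -1.21. Rarity in footprints was thus not particular to AP-1 or MEF2. With footprints widened by 10 bp on each side, CRE joined the 3 motifs above all permuted versions in both libraries, and the homeodomain motif lay below all 13 of its own. In widened footprints the MYOD-type E-box was more frequent than CTCF, with 6287 and 6317 occurrences against 5037 and 4592. The HNF1 motif of liver occurred in no peak of either library. With 1 occurrence in 34.6 Mb of flanks of regions away from promoters, it is too rare for this absence to be informative.

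**Figure D4:**
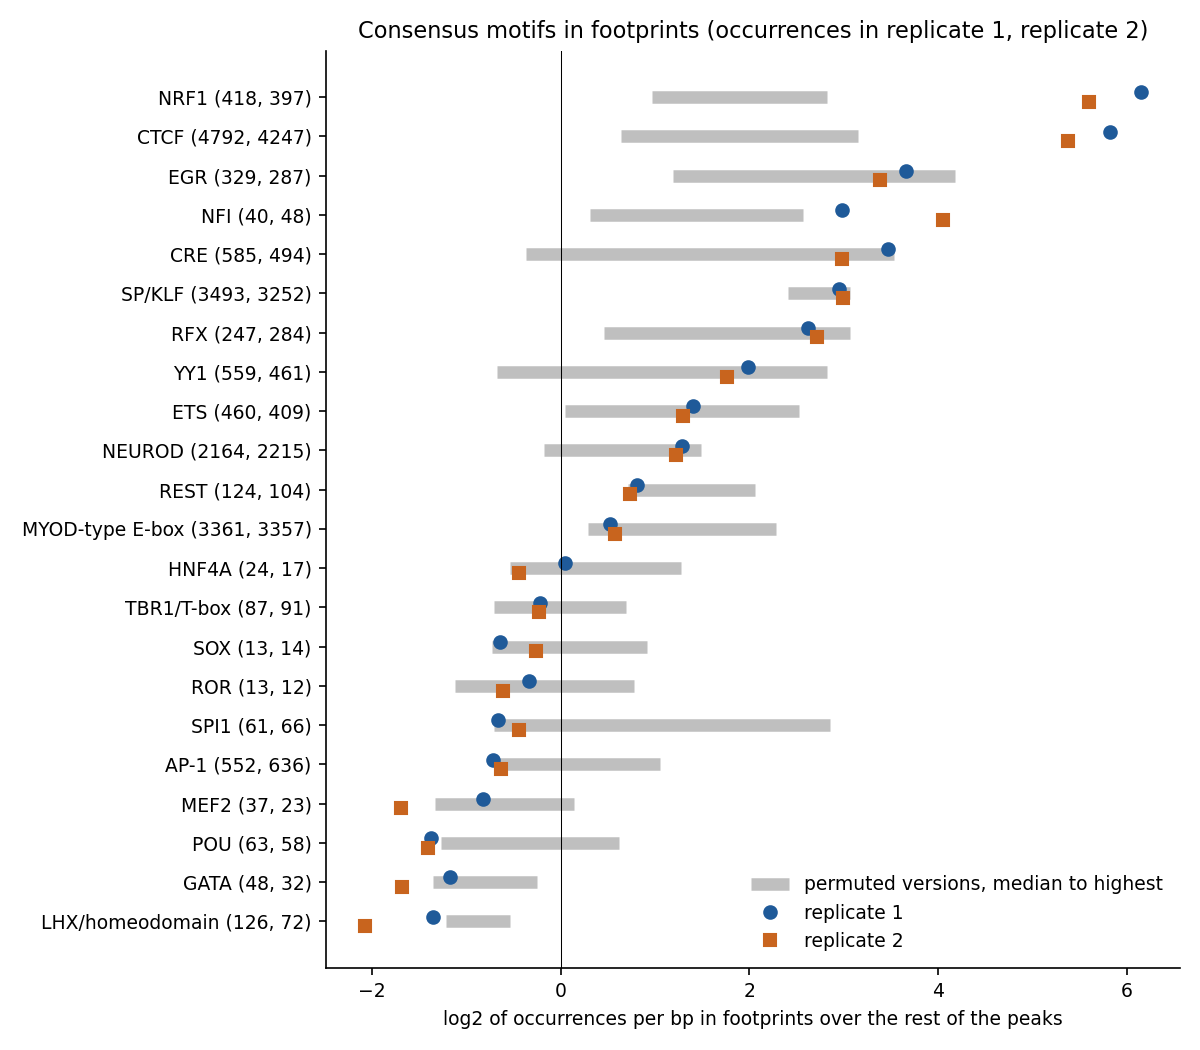
Points give the log2 ratio of a motif's occurrences per bp in footprints over the rest of the peaks (horizontal axis) in replicate 1 (circles) and replicate 2 (squares), with occurrences in brackets; grey bars run from the median to the highest of its letter-permuted versions. CTCF, NRF1 and NFI lie above the bars in both libraries; HNF1, with 0 occurrences, is not drawn.

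The authors' false discovery rate of the cut rate was at most 0.05 over 26.8 Mb in replicate 1 and 24.8 Mb in replicate 2, or 0.945 ± 0.0516% of the chromosomes (SD, n = 2). It was at most 0.001 over 0.522 ± 0.0296% (SD, n = 2).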

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

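Of the tests in this part, the one on genes of the Y short arm was chosen only after the result was seen.

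Chromosome Y held 60 peaks in replicate 1 and 36 in replicate 2, although both libraries are labelled female. The rule for flagging was more than 3 peaks, a limit for a count of 0 that sets no bound on peaks from misplaced reads. None of 8 genes of the short arm (Kdm5d, Eif2s3y, Ddx3y, Uty, Usp9y, Zfy1, Zfy2 and Sry) had a promoter peak in either library. The share of 0 argues against male cells in the sample or a wrong sex label, except for an admixture too small to give peaks. Without a male library, it was not shown that all 8 promoters would have a peak in male cortex. Of the 76 regions on Y, 55 (72.4%, exact 95% interval 60.9 to 82.0%) had a near-identical copy off chromosome Y, against 16 of 300 random autosomal regions with another copy (5.33%, exact 95% interval 3.08 to 8.52%), which for these 55 is consistent with reads from near-identical copies off chromosome Y being placed on Y. Of the 21 regions without such a copy 16 lay between 90 and 92 Mb, where 19 of the regions, with or without a copy, were called in replicate 1 only. The regions without a copy stay open, and besides male cells in the sample no biological explanation was tested.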

How the results depend on the processing

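The alternatives without windows rich in regions of 1 library and with peaks overlapping the other library alone were chosen only after the results were seen. Among the main values, 34 alternatives were labelled as kept and 26 as moved. A count was kept within a fixed ratio, any other value within its spread. These labels cannot show a change of direction. Leaving out 1 of 2 libraries moves a mean share by less than its SD, so such shares were kept by construction. The share of peaks overlapping the other library, 70.3% in the mean, was 55.6% at an overlap of at least 50% of both peaks, 83.2% for the stronger 50% of peaks, 73.5% on the shorter peak list and 72.4% without the windows, and the rho of values was 0.875 for the stronger 50%. The promoter share of 30.5% was 24.6% and 37.2% with promoters of 500 bp and 2.5 kb on each side, which follows from the window size, 41.7% for the stronger 50%, 39.4% on the shorter list and 35.0% for overlapping peaks alone. The 14 lists that differed in promoter peaks became 8 with 1 TSS per gene and 6 against genes matched on promoter CpG content, and 11 to 16 in the other settings, with 16 on the shorter list. The 5 lists that differed in peak number became 3 with the gene body alone, 0 with 50 kb on each side, 3 for the stronger 50%, 3 on the shorter list and 3 for overlapping peaks alone. The X to autosome ratio of 0.389 was 0.593 per protein-coding gene, 0.243 for the stronger 50%, 0.349 on the shorter list and 0.355 for overlapping peaks alone. Of footprints, 88.4% lay wholly inside a peak and 65.0% overlapped a peak of the shorter list, against 90.4% that overlapped one of the main list. The share that overlapped the other library was 33.2% at 50% of both, against 46.5%. At a false discovery rate of at most 0.01 and 0.001 the share of the chromosomes was 0.710% and 0.522%. Among single lists, 1 changed its direction with a test past the threshold, inhibitory neurons on the shorter list, with a log2 odds ratio of -2.16 against 0.26. Other changes of sign had no such test, as for forebrain factors with 1 TSS per gene (-0.39 against 1.99). The cause was not tested for these changes, except where the construction shows it. Among the other values, single lists for the most part, 417 stayed on their side of the threshold, 44 lost the call, 17 gained one and 2 moved. Of the lists that passed for promoter peaks, Hox and germ cell genes passed in all 8 alternatives, and pan-neuronal, immediate early, liver and circadian genes in 7. Leaving out a library gave no value for overlaps or the rho. Every alternative fixed in advance was run. The overlap between libraries was lowest for weak peaks, and no sequencing depth is given in the sources used here.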

Other observations

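The gene families, the motif scan of distal regions and the tests of a lower local calling threshold were chosen only after the results were seen.

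Gene families grouped by symbol, of which some members are also in the fixed lists, ranged from all members with a promoter peak to almost none. All 72 cytosolic ribosomal protein genes, with a median promoter value of 3.79, and all 36 genes of respiratory complex I had a promoter peak in both libraries, as did 37 of 39 proteasome genes. Of 1135 olfactory receptor genes 12 (1.06%) had one, and of 329 vomeronasal receptor genes 1 (0.304%), against 61.5% of protein-coding genes. In replicates 1 and 2 alone the counts were 25 and 23 olfactory and 4 and 2 vomeronasal genes. Keratins (6 of 53), beta-defensins (2 of 42), cytochromes P450 (15 of 75) and chemokines (8 of 31) were also low. Of 17 synaptotagmins 16 had one, of 39 kinesins 35, of 92 potassium channels 67, of 26 voltage-gated calcium channels 21 and of 14 voltage-gated sodium channels 8. Zfp zinc finger genes (338 of 394) and replication-dependent histone genes (56 of 66) were high and solute carriers (239 of 371) did not pass. Over these 20 families Fisher's exact test gave adjusted p of 0.787 for sodium channels, 0.272 for solute carriers, 0.0499 for calcium channels, 0.0287 for potassium channels and 0.00582 or less for the others. No family, the protocadherins below included, was compared with genes matched on promoter CpG content, on which the share with a promoter peak depends. A high or low share is therefore not shown to be particular to a family, and genes of a family need not be independent units.

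In the clustered protocadherins, adhesion proteins of which each neuron expresses a few, the promoter peaks sat at few genes. Of 14 alpha genes Pcdhac1 (1.67) and Pcdhac2 (1.05) had one in both libraries, of 22 beta genes Pcdhb4 (0.324) and Pcdhb7 (0.295), with 5 beta genes in replicate 1 alone, and of 21 gamma genes Pcdhgc3 (3.18), Pcdhgc5 (1.54) and Pcdhga12 (0.846). All 3 clusters stood below other genes (Fisher's exact test, adjusted p = 0.000536, 1.05e-06 and 2.14e-05), and members of a cluster are not independent units.

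Regions called in both libraries and away from promoters, 38834 in number, were also scanned for motifs against flanks. Above all letter-permuted versions were CTCF with a log2 density ratio of 6.70, RFX with 3.96, CRE with 2.08, AP-1 with 1.51, SP/KLF with 1.36 (of 8 permuted versions), MEF2 with 0.83, POU with 0.14 and the homeodomain motif with -1.04 (of 13 permuted versions, the highest at -1.07). MEF2 and AP-1, which were not above their permuted versions in footprints, were so in distal regions. NRF1 and NFI, which were in footprints, exceeded 83 and 99 of 100 permuted versions in distal regions, NRF1 with a log2 ratio of 3.09 against 4.19 in the highest.

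Peaks called in 1 library only were crowded into certain windows. In replicate 1, 94 windows of 50 kb held 10 or more such regions and 5.35% of all of them, the densest at Mid1 on X (169950001 to 170000000) with 28. In replicate 2, 232 windows held 15.7%, the densest at Cln8 on chromosome 8 (14850001 to 14900000) with 63. Their median values were low, 0.215 against 0.396 elsewhere in replicate 1 and 0.160 against 0.451 in replicate 2. Among the 10 genes with the densest peaks, 1 (Acap3) kept its place once 321 such windows were left out.

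A local gain of accessible DNA or of copies in the calling library would raise its values at the shared regions in these windows, but the log2 ratio there differed from elsewhere by -0.0204 in the mean of the libraries, over 392 and 801 regions. Sequence with near-identical copies in the genome is also argued against, since 17 of 300 sampled regions had another copy inside the windows (5.67%, exact 95% interval 3.34 to 8.92%) and 17 of 300 outside, a ratio of 1. In replicate 2, peaks at the edge of calling, with a lowest false discovery rate between 0.01 and 0.05, had a median value of 0.106 in the windows and 0.428 elsewhere, a ratio of 0.247, and in replicate 1 the values were 0.302 and 0.379, a ratio of 0.799. A lower local calling threshold stays open in both, since the low values of replicate 2 in these windows had been seen before the test and the ratio of replicate 1 falls between the bounds set. Besides a gain of accessible DNA, no biological explanation was tested.

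The lower density of peaks on X had several parts. At promoters the ratio of X to autosomes per Mb was 0.490 and 0.492, and for other peaks 0.352 and 0.338. Of 948 X genes 45.1% had a promoter peak in both libraries, against 52.5% in autosomal lists matched on promoter CpG content (95% range 50 to 55.1%), at percentile 0 of these lists. This share counts the same peaks as the density, so it describes the pattern and cannot test a cause of it. The median promoter value of the 428 X genes with a peak was 1.30 against 2.17 in matched lists (95% range 1.95 to 2.34), also at percentile 0, consistent with lower values at X promoters, as 1 silent X would give. With no male library and no split by parental allele here, other differences between X and autosomes could account for it as well.

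Of the 20 regions with the highest mean value, 10 (50%, exact 95% interval 27.2 to 72.8%) had another copy in the genome, against 5.33% of random autosomal regions.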
